A study of Nematostella vectensis with 123 samples.

How the data were processed

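RNA from 123 single embryos of the starlet sea anemone Nematostella vectensis was measured. Per the labels' protocols, embryos were picked at the 4-cell stage and incubated at 20 °C. Each was frozen singly for Trizol extraction. Libraries were made with CEL-Seq, a method that gives each embryo a barcode and reads the 3' end of polyadenylated RNA after linear amplification. The library was treated with DSN, a nuclease for double-stranded DNA that lowers the share of abundant molecules. CASAVA 1.8, Bowtie2 2.1.0 and HTSeq 0.5.4p3 are named in the submitters' processing notes. The genome build and the annotation were not given in the sources used here, nor was the amount of spike-in RNA added per embryo.

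The authors deposited whole-number counts per embryo for 40499 transcript models, 92 ERCC spike-ins (synthetic RNAs) and 5 rows of unassigned counts. These deposited counts were not normalized. The unassigned rows and the spike-ins stayed out of library sizes and tests of transcript models. Counts assigned to no feature were a median of 10.0% of all counts per embryo (range 4.27 to 43.1%), and unaligned counts a median of 37.0% (30.0 to 71.0%). The rows for ambiguous and for not uniquely aligned counts held 0 counts. Transcript models shared 33279 identifier stems, so models with the same stem were counted apart. Whether a stem stands for a locus was not given. The stem 63571 alone covered 3153 models and held a mean of 13.3% (window 2) to 21.2% (window 6) of gene counts. The stem 12653 covered 539 models and held 8.92% (window 6) to 10.3% (window 1). Counts that fall on overlapping or near-identical models are uncertain.

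None of the 40499 identifiers matched the 38762 genes of the reference table used for names (assembly jaNemVect1.1), so the files and the table pair no model with a gene name. The gene-list tests planned before the data were examined could not be run, and genes are given by model identifier. The naming rule, fixed beforehand, took the called models with the largest rise and fall whose mean was at least 10 CPM in the higher window. Its requirement of a gene description could not be met, so 2 models per direction are printed.

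The labels give 1 time point per embryo and no replicate groups. They state no unit. The numbers were read as minutes, since the protocol collected every 20 min. They run to 4320 (72 h), past the 48 h that the protocol names. Embryos were grouped into 6 windows of 12 h (720 min), which held 20, 17, 18, 31, 18 and 19 embryos. Label time rises with embryo number up to embryo 73 (embryo 50, labelled -20, excepted) and falls from embryo 74 to embryo 123. These number blocks were treated as a possible technical batch. Smaller sets of embryos within a block were not modelled. Windows 1 to 3 hold embryos 1 to 73 only, windows 5 and 6 hold embryos 74 to 123 only, and window 4 holds both. Embryos in a window differ in age, so the spread within a window includes the trend over time. Nothing in the labels says that the embryos came from separate clutches, so p-values measure the spread between these embryos.

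Embryos with fewer than 50000 gene counts were left out: embryo 10 of window 1 and embryo 111 of window 4. The 121 embryos used had 56536 to 2646585 gene counts (median 827571). A model at 0 in an embryo of median depth could have been present at up to 3.63 CPM, taking 3 counts as the limit. This limit covers counting error only, since the files hold no count of distinct molecules. Errors given with values are spreads between embryos. No pair of embryos in a window agreed within sampling noise: the smallest chi-square per degree of freedom was 5.13.

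Adjacent windows, and window 6 against window 1, were compared with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3. A model was called changed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Standard errors were taken as the absolute log2 fold change divided by the square root of F. A natural cubic spline of label time with 5 degrees of freedom was tested over all 121 embryos with the same kind of test. There a model was called changed at an adjusted p under 0.05 alone, without a fold threshold. Number blocks were compared over 11 pairs of embryos with equal label time, with label time as a block. Alternatives included DESeq2 1.42.0, voom with quantile normalization in limma 3.58.1, other filters, other library minimums and fits within 1 number block. Spike-in scaling and the fit without 9 embryos of unusual totals were added after the data were seen. The 9 were picked by hand and not by depth. Embryos 7, 32, 58 and 96 were high in counts assigned to no feature. Embryos 3, 28, 54 and 92 were high in unaligned counts, and embryo 27 had the lowest ratio of gene to spike-in counts.

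RNA content was taken as gene counts per spike-in count, on a log2 scale. The ratio covers the polyadenylated RNA that was captured, and the spike-in amount per embryo was not given. It is a relative measure only, and a change in capture cannot be told from a change in RNA content. Detected models were counted after each embryo was thinned to 100000 gene counts, for which 5 of the 123 embryos were too shallow. Differences between windows used two-sided permutation tests with 100000 resamples, and pairs used exact two-sided sign-flip tests. Benjamini-Hochberg adjustment covered the 6 comparisons of each measure. Principal components were taken from log2 CPM of the 2000 most variable models. Label time was also predicted for each embryo as the mean of the 5 nearest other embryos by Pearson correlation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

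The fits were tested on simulated data, with counts drawn at the means and depths of the real embryos. In the fits between groups, a change counted as called there at an adjusted p under 0.05, without the fold threshold. Each simulation held a planted set of changed models of fixed size. With fewer true changes the adjustment is stricter, and the shares called would be lower. Under the full calling rule the shares of true changes called could only be equal or lower. In the 5 comparisons of adjacent windows and in window 6 against window 1, 88 to 99% of 4-fold changes and 30 to 53% of 2-fold changes were called. For window 5 against window 4 within embryos 74 to 123, 72% of 4-fold and 19% of 2-fold changes were called. For the matched pairs these shares were 64% and 11%. False calls were 1.34 to 2.96% of the calls in the 6 window comparisons and 1.32% in the pairs. In the time-course fit, simulated on 3331 models with 160 changed 4-fold, 79.4% of the changed models were called and 8.63% of the calls were false, above the nominal 5%.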

Results

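The series followed gene expression through early development of Nematostella vectensis, a cnidarian, in 123 single embryos collected from the 4-cell stage onward. After the count minimum, windows 1 to 6 held 19, 17, 18, 30, 18 and 19 embryos. Median gene counts per embryo were 788770 (range 206062 to 1630063), 862248 (56536 to 1706574), 1100248 (394965 to 2646585), 832038 (134581 to 1970889), 1223726 (69854 to 2029785) and 758031 (58680 to 2113426). Each embryo was a single sample of its own time, so the labels give no replicates at equal time within a number block.

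The main axis of expression followed label time in embryos 1 to 73 and was flat in embryos 74 to 123. Principal component 1 held 49.2% of the variance. Its scores lay near the low end in embryos of the earliest hours and were much higher by 24 h. In embryos 1 to 73 from 24 h on they lay between 2.75 (embryo 43) and 44.8 (embryo 66), against -144 in embryo 9. Embryos 74 to 123 hold label times from 39.3 h on only, so their flat relation covers late times alone. No correlation was run for the late embryos of the first block by themselves. Over all 121 embryos the correlation with label time was r = 0.82 and rho = 0.80 (permutation test, two-sided p = 1e-05 for each, the smallest it can give; adjusted p = 1.5e-05 over 3 relations). Without the 2 embryos farthest from the median time r was 0.80. Within embryos 1 to 73 r was 0.90 and rho 0.91 (n = 72, p = 1e-05 for each, adjusted 1.5e-05), and r was 0.89 without the 2 farthest. Within embryos 74 to 123 r was 0.06 (permutation p = 0.70, adjusted 0.70) and rho 0.10 (p = 0.49, adjusted 0.49; n = 49), so the pooled relation did not hold in this block. Without the 2 farthest r was -0.03. The time predicted from the 5 nearest embryos missed the label by a median of 90 min in embryos 1 to 73 and 352 min in embryos 74 to 123. Shuffled labels gave medians of 762 and 528 min (permutation p = 0.000999, the smallest that 1000 shuffles can give, and p = 0.0050).

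**Figure D1:**
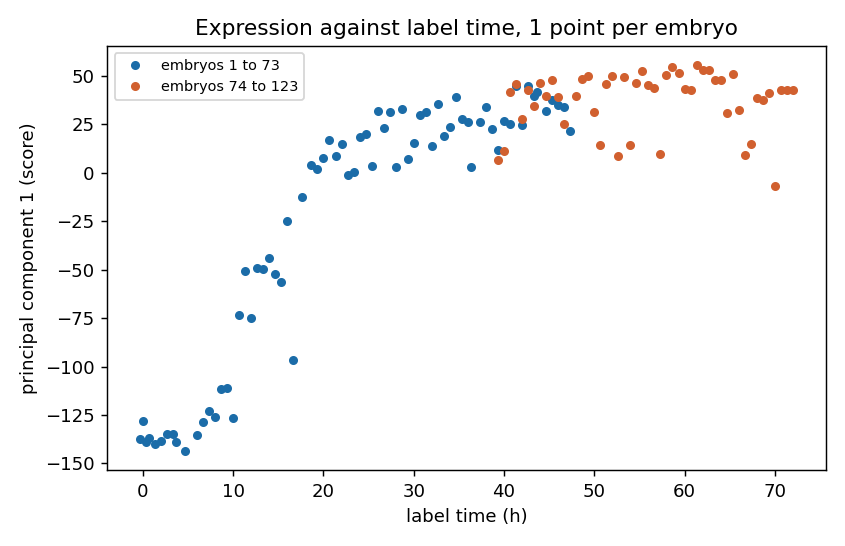
Score on principal component 1 against label time in hours, with 1 point per embryo and a colour for each number block. Scores rise with time in embryos 1 to 73 (r = 0.90) and show no such relation in embryos 74 to 123 (r = 0.06), which start at 39.3 h.

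Gene counts per spike-in count rose with label time in embryos 1 to 73. The geometric mean of gene counts per spike-in count was 2.30 in window 1, 3.29 in window 2, 5.17 in window 3 and 5.48 in the 18 window 4 embryos of this block. Within these 18 it was 3.94 in the 9 embryos before 42 h and 7.61 in the 9 from 42 h on. That log2 step was 0.95 ± 0.32 (SE, exact two-sided permutation test, p = 0.0082), at a boundary chosen after the data were seen. Within embryos 1 to 73 the log2 ratio was correlated with label time (r = 0.58, rho = 0.63, n = 72, permutation p = 1e-05 for each, the smallest it can give, adjusted 2e-05 over 2 relations). Without the 2 embryos farthest in time r was 0.57. This relation was chosen after the spike-in rows were seen. In embryos 74 to 123 the ratio was higher, 11.5 in window 4, 13.5 in window 5 and 10.3 in window 6, and r was -0.08 (p = 0.57, adjusted 0.57) and rho -0.14 (permutation p = 0.34, adjusted 0.34, n = 49). The steps between adjacent windows were +0.51 ± 0.27 on the log2 scale (SE, p = 0.043, adjusted p = 0.086) from window 1 to 2, and +0.65 ± 0.30 (p = 0.023, adjusted p = 0.068) from window 2 to 3. Neither passed the permutation test after adjustment. Without the 9 embryos of unusual totals, picked by hand after the data were seen, the step from window 1 to 2 was +0.71 ± 0.17 (permutation test, adjusted p = 0.00072). The 9 include embryo 27, with a ratio of 0.254.

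More transcript models were detected at equal depth in later embryos of the same block. At 100000 gene counts, 12801 ± 698 models (SD, n = 19) were detected in window 1, 13386 ± 575 (n = 16) in window 2 and 14093 ± 388 (n = 18) in window 3. The rise of 584 ± 215 (SE) from window 1 to 2 passed the permutation test (adjusted p = 0.022), as did that of 707 ± 170 from window 2 to 3 (adjusted p = 0.0013). Without thinning the means were 18250 ± 2124, 19313 ± 3678 and 21728 ± 2029 models (SD), and neither step passed (adjusted p = 0.58 and 0.051). From window 3 to the window 4 embryos of the same block (14244 ± 625, n = 18) the step was 151 ± 173 (adjusted p = 0.53). In embryos 74 to 123 the means were 12511 ± 1541 in window 4 (n = 12), 12897 ± 1683 in window 5 (n = 17) and 12547 ± 1409 in window 6 (n = 18). The steps between these did not pass (adjusted p = 0.53 for each).

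**Figure D2:**
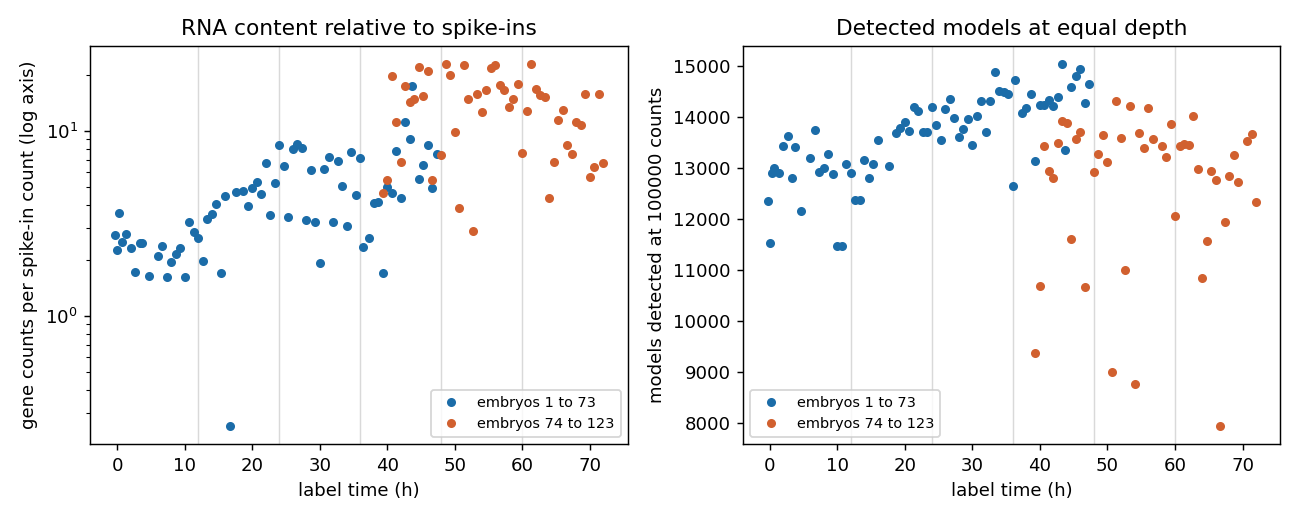
Gene counts per spike-in count on a log axis (left) and transcript models detected at 100000 gene counts (right) against label time in hours, with 1 point per embryo, coloured by number block; grey lines mark the window boundaries. Mean detection rises from 12801 models in window 1 to 14093 in window 3, and at equal label time embryos 74 to 123 have the higher ratio and fewer detected models in 11 of 11 pairs.

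Among adjacent windows, the broadest change in transcript levels lay between window 1 (below 12 h) and window 2 (12 to 24 h). Of 11348 models tested, 5381 changed, 2980 of them higher and 2401 lower in window 2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Model Nv.T1.62403.1 rose from 3.28 ± 6.60 CPM (SD, n = 19) to 1557 ± 2257 CPM (n = 17), a log2 fold change of 9.13 ± 0.97 (SE, adjusted p = 2.6e-09). Model Nv.T1.49894.1 rose from 2.79 ± 3.82 to 256 ± 361 CPM, a log2 fold change of 6.69 ± 0.66 (adjusted p = 9.9e-10). Among those that fell, Nv.T1.1346.1 went from 121 ± 87.0 to 8.95 ± 25.6 CPM (log2 fold change -5.24 ± 0.73, adjusted p = 1.9e-07). Among embryos within 360 min of the boundary its log2 fold change was -2.62 ± 0.92 and was not called (adjusted p = 0.0504). Nv.T1.6111.2 went from 48.1 ± 37.3 to 2.97 ± 6.40 CPM (log2 fold change -4.98 ± 0.66, adjusted p = 8.2e-08). Nv.T1.62403.1, Nv.T1.49894.1 and Nv.T1.6111.2 did not pass the filter on low counts among embryos within 360 min of the boundary and were not tested there. Scaled to the spike-ins, 5909 models changed and 77.7% of them were higher, against 55.4% with TMM. The other settings gave 47.8% (quantile normalization) to 59.8% (1 fit over all windows), and 50.3% without embryo 50. The median log2 fold change of all models was 0.65 with spike-in scaling and 0.06 with TMM. Between embryos within 360 min of the boundary, 9 on each side, 1640 models changed with TMM and 174 with spike-in scaling (92 higher, 82 lower). Without embryo 27, whose gene to spike-in ratio was the lowest, these counts were 2351 and 2093.

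From window 2 to window 3 (24 to 36 h), 1303 of 12210 models changed, and 904 of these were higher in window 3. Nv.T1.31889.1 rose from 6.40 ± 13.2 CPM (SD, n = 17) to 241 ± 479 CPM (n = 18), a log2 fold change of 5.64 ± 0.95 (SE, edgeR adjusted p = 0.00010). Nv.T1.3260.1 rose from 8.00 ± 18.2 to 285 ± 561 CPM (log2 fold change 5.59 ± 0.96, adjusted p = 0.00012). Embryo 49 held 37.7% and 37.9% of their window 3 CPM, and without it the log2 fold changes were 4.98 ± 0.89 (adjusted p = 0.00021) and 4.92 ± 0.90 (adjusted p = 0.00027). With voom and quantile normalization they were 2.93 ± 1.03 (adjusted p = 0.032) and 3.23 ± 1.06 (adjusted p = 0.022). The largest falls rested on 1 library. Nv.T1.71029.1 was at 1352 ± 5536 CPM in window 2 and 12.8 ± 7.56 CPM in window 3 (log2 fold change -6.65 ± 1.23, adjusted p = 0.00024), and embryo 32 alone held 99.3% of its summed window 2 CPM. Without that embryo it was too low to be tested. Nv.T1.71029.2 had a log2 fold change of -3.78 ± 0.88 (adjusted p = 0.0021), and of 0.44 ± 0.39 (adjusted p = 0.44) without embryo 32. With spike-in scaling 2003 models changed, 95.9% of them higher, against 69.4% with TMM (median of all models 0.49 against 0.04). Within 360 min of the boundary 138 models changed with TMM and 143 with spike-in scaling.

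Window 4 (36 to 48 h) differed from window 3 in 246 of 13069 models, 188 higher and 58 lower. Within embryos 1 to 73 alone, 204 models changed (141 higher, 63 lower), and 101 of these had also changed, in the same direction, with both blocks together. Of the 246 models, 212 could be tested within embryos 1 to 73, and 210 of these moved in the same direction there, with a median log2 fold change of 1.16 against 1.32, in libraries shared with the call. Nv.T1.49832.1 rose from 0.262 ± 0.963 CPM (SD, n = 18) to 30.2 ± 41.9 CPM (n = 30), a log2 fold change of 6.54 ± 0.90 (SE, edgeR adjusted p = 2.1e-05). With voom and quantile normalization it was 3.15 ± 0.78 (adjusted p = 0.0071). This model was too low to be tested within embryos 1 to 73 or without embryo 67. Nv.T1.71029.1 rose with a log2 fold change of 4.92 ± 0.98 (adjusted p = 0.0018). Embryo 58 held 91.4% of its window 4 CPM, and without that embryo the log2 fold change was 1.35 ± 0.40 (adjusted p = 0.031). It was not called with quantile normalization (adjusted p = 0.17). Nv.T1.63571.9155 fell from 1199 ± 1365 to 202 ± 370 CPM (log2 fold change -2.38 ± 0.67, adjusted p = 0.025; -1.71 with adjusted p = 0.18 within embryos 1 to 73). It was not called with the number block as a covariate (adjusted p = 0.17) or at a minimum of 500000 gene counts (adjusted p = 0.077). It belongs to the stem with 3153 models, so counts shared with near-identical models are possible. Nv.T1.12385.5 had a log2 fold change of -2.25 ± 0.52 (adjusted p = 0.0058), but of 0.63 ± 0.27 (adjusted p = 0.17) without embryo 54, and was not called within embryos 1 to 73 (adjusted p = 0.083). With the number block as a covariate 138 models changed, and within 360 min of the boundary none did (935 at an unadjusted p under 0.05 with edgeR). With spike-in scaling 1300 changed, 98.7% of them higher, against 76.4% with TMM (median of all models 0.54 against -0.03). Within embryos 1 to 73 spike-in scaling gave 73 changed models, 47 higher and 26 lower, and a median of -0.02.

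Window 5 (48 to 60 h) differed from window 4 in 333 of 13355 models, 123 higher and 210 lower, but these windows also differ in number block. Within embryos 74 to 123 alone (18 against 12 embryos) 5 of 12626 models changed, 1 of which was among the 333. With the number block as a covariate 2 models changed. Nv.T1.8229.1 was at 4.34 ± 6.00 CPM (SD, n = 30) in window 4 and 29.8 ± 28.9 CPM (n = 18) in window 5 (log2 fold change 2.58 ± 0.47 SE, edgeR adjusted p = 0.00077). Within embryos 74 to 123 its log2 fold change was 2.47 (adjusted p = 0.21). Nv.T1.45254.1 was at 3.91 ± 5.77 and 24.2 ± 30.3 CPM (log2 fold change 2.58 ± 0.53, adjusted p = 0.0027; 2.64 with adjusted p = 0.28 within the block), and was too low to be tested without embryo 94. Nv.T1.39482.1 was at 82.2 ± 115 and 6.14 ± 11.7 CPM (log2 fold change -3.95 ± 0.80, adjusted p = 0.0024) and was too low to be tested within the block. Nv.T1.63571.9155 had a log2 fold change of -3.93 ± 0.76 (adjusted p = 0.0014), and of -0.33 (adjusted p = 1.0) within the block. None of these 4 models was called with the number block as a covariate, and within 360 min of the boundary no model was (824 at an unadjusted p under 0.05 with edgeR). With spike-in scaling 1119 models changed, 99.0% of them higher, against 36.9% with TMM (median of all models 0.71 against -0.07). Within embryos 74 to 123 it gave 2 changed models, both lower, and a median of 0.15. DESeq2 gave 24.6% higher and quantile normalization 64.9%.

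No model changed from window 5 to window 6 (60 to 72 h), of 10636 tested with edgeR. At an unadjusted p under 0.05 there were 473 models, and DESeq2 called 0. In the simulated data 88% of 4-fold and 30% of 2-fold changes reached an adjusted p under 0.05 at these depths and numbers, without the fold threshold. These shares hold for the planted set of changed models, and with fewer true changes they would be lower. With spike-in scaling 11 models changed, all lower (median of all models -0.52 against -0.01 with TMM). The count was 8 in 1 fit over all windows and 2572 without a filter on low counts.

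**Figure D3:**
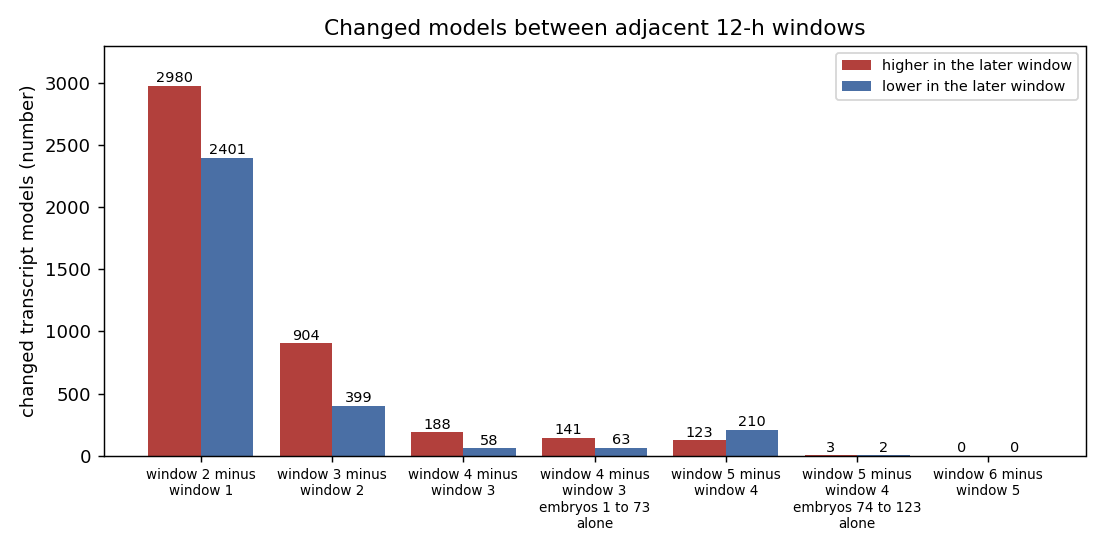
Number of transcript models called higher or lower in the later of 2 adjacent 12-h windows, over all embryos and, where both windows hold embryos of 1 block, within that block alone. The count falls from 2980 higher and 2401 lower at the earliest boundary to 0 at the latest, and within embryos 74 to 123 window 5 differs from window 4 in 3 higher and 2 lower models.

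The ends of the series, window 6 against window 1, differed in 6190 of 10651 models, 2847 higher and 3343 lower. Nv.T1.9257.3 had 0 counts in the 19 window 1 embryos and 639 ± 797 CPM (SD, n = 19) in window 6. Pooled over the embryos of window 6 it was at 832 CPM, at least 4326-fold higher than the limit of 0.192 CPM that 3 counts pooled over window 1 allow (edgeR adjusted p = 2.2e-12). Nv.T1.7570.1 also had 0 counts in window 1, was at 385 ± 393 CPM in window 6 and, pooled in the same way, at 463 CPM, at least 2407-fold above that limit (adjusted p = 3.2e-12). Nv.T1.10814.8 fell from 605 ± 204 to 1.23 ± 4.56 CPM (log2 fold change -8.94 ± 0.54 SE, adjusted p = 4.3e-18). Nv.T1.7341.4 fell from 584 ± 265 to 5.55 ± 24.2 CPM (log2 fold change -8.72 ± 0.72, adjusted p = 4.2e-14). Both models had 11 counts in window 6, those of Nv.T1.10814.8 in 2 embryos and those of Nv.T1.7341.4 in 1. The size of these falls is therefore uncertain. The split by direction depended on the scaling: 46.0% were higher with TMM, 28.7% with median-ratio size factors, 28.9% with DESeq2 and 94.7% with spike-ins. It also depended on other choices. Without a library minimum 52.0% were higher, and in 1 fit over all windows 52.8%. With the number block as a covariate in that fit 8127 models changed, 62.1% of them higher. The remaining settings gave 44.8% (quantile normalization) to 49.6% (no filter on low counts). The median of all models was 1.84 with spike-in scaling and -0.14 with TMM. These windows differ in number block throughout.

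Over the whole series 15793 of 19052 models (82.9%) changed with label time in the spline fit, without a fold threshold. A fitted log2 range of at least 1 was found for 15504 of these, and of at least 3 for 7520. The fitted maximum of the 15504 lay in window 1 for 5660 models, window 2 for 2189, window 3 for 2459, window 4 for 757, window 5 for 2098 and window 6 for 2341. With median-ratio size factors 8882 peaked in window 1. With 3 degrees of freedom 704 peaked in window 2 and 3634 in window 3, and with 8 these were 2876 and 1302. Of the models changed in the main fit as well, 70.4% and 71.3% kept their peak window. In the main fit 5279 peaked at the first label time and 1744 at the last, where the spline ends. With the number block as a covariate 14204 of 19509 models changed. Within embryos 1 to 73 alone 15274 of 18695 models changed, and within embryos 74 to 123 alone 250 of 19069 did (1.31%).

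Embryos of equal label time differed between the number blocks. Over 11 pairs between 39 and 47 h, 255 of 11881 models changed (112 higher and 143 lower in embryos 74 to 123; edgeR with label time as a block). DESeq2 called 1375, and spike-in scaling 2860, of which 2833 were higher. The gene to spike-in ratio was 1.98-fold higher in embryos 74 to 123, in 11 of 11 pairs (exact sign-flip test, p = 0.00098, the smallest it can give; adjusted p = 0.0059). Detected models at equal depth were fewer by a mean of 2003, again in 11 of 11 pairs (12385 ± 1550 against 14388 ± 511, SD, exact p = 0.00098, adjusted p = 0.0029). Before thinning, embryos 74 to 123 had fewer gene counts in each pair but that of embryos 121 and 63. That pair had 13434 against 14243 models, whereas the shallow embryo 123 (134581 gene counts) had 9365 against 13143 in embryo 61. Thinning equalizes counts and not the number of distinct molecules behind them. How much of the mean of 2003 comes from shallow libraries was not tested. Spike-ins detected at 20000 spike-in counts were also fewer, 47.3 ± 3.68 against 55.5 ± 2.22 (10 of 10 pairs, exact p = 0.0020, adjusted p = 0.012). Spike-in counts before thinning were lower in embryos 74 to 123 in each of these pairs, so the same limit holds. Of 61 spike-ins tested with edgeR, 6 differed at an adjusted p under 0.05, and 1 of these by at least 2-fold.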

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

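The signal flagged here lies in counts outside the transcript models. The test of 500 to 2000 CPM models was set before its result was seen, and the other tests in this part were chosen after. Embryos 7, 32, 58 and 96 had 7.51, 3.11, 1.81 and 4.985 counts assigned to no feature per gene count. The other 117 embryos used had at most 0.344.

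These 4 embryos are spaced by 25, 26 and 38 in number, and they were the 4 highest in models Nv.T1.71029.1 and Nv.T1.71029.2. Embryos 3, 28, 54 and 92 lie at the same spacing and were the 4 highest in Nv.T1.12385.5. Their unaligned counts were 71.0, 58.7, 47.5 and 66.5%, against a median of 36.8% in the other embryos. Embryo 54 held 87.2% of the window 3 CPM of Nv.T1.12385.5, which fell from window 3 to 4. Of 237 models that reached 2000 CPM, 26 had their 4 highest embryos at exactly this spacing, from 12 different starting embryos between 2 and 21, against 0 of 100000 random sets of 4 embryos. A developmental stage shared by these embryos is argued against by models picked on embryos 1 to 73 alone and then read in embryos 74 to 123. Among 1226 models that reached 500 CPM in embryos 1 to 73, 44 had their 3 highest embryos of this block at the spacing 25 and 26, leaving out the sets that start at embryos 3 and 7. In embryos 74 to 123 the embryo 38 numbers further on was the highest of 49 for 38 of the 44 models, against 0.898 expected by chance. It was above its neighbours in number, which lie next to it in label time, for 44 of 44, with a median log2 ratio of 4.36 (quartiles 3.02 and 5.09). The distance of 38 came from the 26 models, however, and many of these are among the 44. Their high embryo was known beforehand, so 0.898 is no chance level for them. For the rest of the 44 this embryo was also above its neighbours in each case, and the highest of 49 in most. A library position used once in each of 4 sets of embryos, such as a shared CEL-Seq barcode, is a candidate explanation. It called for the same spacing among 1229 models with a maximum of 500 to 2000 CPM, where 20 showed it and the next most frequent spacing occurred in 10. The labels name no barcodes, so a barcode and another feature of the position stay open. Such sets would also divide embryos 1 to 73 along label time. Among the 44 models the high embryo in embryos 74 to 123 lay between embryos 91 and 110, close to window 5 (embryos 93 to 110). Changes within either block, among them those between window 5 and its neighbours within embryos 74 to 123, could then mix time with set, which was not tested. The 26 models took a median of 0.330% of an embryo's gene counts and at most 9.44%.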

How the results depend on the processing

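Spike-in scaling, the fits without 9 embryos and the fits within blocks of the time course were chosen after the data were seen, as were all alternatives for RNA content and detected models. Of 24 main results, 14 stayed on their side of the threshold and within 1.5 times, or within their spread, under each alternative run for them. No filter on low counts gave 14340 (window 2 against 1), 3070 (3 against 2), 1430 (4 against 3), 3003 (5 against 4), 2572 (6 against 5) and 17454 changed models (6 against 1), with more models tested. A minimum of 5 CPM in 9 embryos gave 8863 (2 against 1), 385 (4 against 3) and 10485 (6 against 1). Embryos within 360 min of the boundary, fewer per side, gave 1640, 138, 0 and 0 for the boundaries from 12 to 48 h. A single fit over all windows gave 8288 (2 against 1), 578 (5 against 4), 8 (6 against 5) and 9899 (6 against 1). No fold threshold gave 2866 (3 against 2) and 625 (4 against 3). Quantile normalization gave 391 (4 against 3) and 667 (5 against 4), and DESeq2 629 (5 against 4). The number block as a covariate gave 138 (4 against 3) and 2 (5 against 4), and embryos 74 to 123 alone gave 5 (5 against 4). Spike-in scaling gave 2003 (3 against 2), 1300 (4 against 3), 1119 (5 against 4) and 11 (6 against 5), and within 1 block 73 (4 against 3) and 2 (5 against 4). In the time course 250 models changed within embryos 74 to 123. The matched pairs gave 1375 with DESeq2, 476 at 5 CPM in 6 embryos, 457 without the time block and 2860 with spike-in scaling. The cause of these shifts was not tested where the setting itself does not show it.

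The RNA content step from window 1 to 2 passed its permutation test without the 9 embryos (0.71, log2) and at 500000 gene counts (0.87). The block difference at equal time was 1.08 at 500000 counts with adjusted p = 0.062, over fewer pairs. Directions reversed for Nv.T1.71029.1 (3 against 2) with DESeq2 (0.45) and without the 9 embryos (0.31), and for Nv.T1.71029.2 likewise (0.25 and 0.40). Nv.T1.12385.5 (4 against 3) reversed with DESeq2 (0.36), quantile normalization (0.032) and without the 9 embryos (0.64). Each has 1 library with most of its counts. No paired analysis between windows was possible because the labels give no replicate numbers shared between them. Gene-list tests and their alternatives were not run, since no identifier matched a name. In a single embryo of median depth a model at 0 counts may stand for up to 3.63 CPM.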

Other observations

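All tests in this part other than the other splits of the embryos were chosen after the result they bear on was seen. Of those splits, the ones within 1 number block were added later.

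Transcript models that were near absent before 12 h appeared in each later window. In window 1, 12934 models had 3 counts or fewer over 15594935 gene counts. Of these, 479 later averaged at least 10 CPM and were counted in a share of at least 0.5 of the embryos of a window. They passed this mark earliest in window 2 for 87 models, in window 3 for 153 and in window 4 for 66 among embryos 1 to 73. A further 68 passed it next among the window 4 embryos numbered 74 to 123, 68 in window 5 and 37 in window 6, where the block differs as well. In the other direction, of 11928 models that passed the same mark in window 1, 5 had 3 counts or fewer in window 2 and 37 in window 6.

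With TMM scaling, more models changed between 6-h spans before 24 h than after, within embryos 1 to 73. There 623 models changed at 6 h, 1640 at 12 h, 1521 at 18 h, 138 at 24 h, 71 at 30 h, 0 at 36 h and 0 at 42 h, with 8 to 10 embryos on each side. Spike-in scaling gave 552, 174, 1575, 143, 32, 0 and 3164, and 3 of these counts moved with single libraries. Without embryo 27 the count was 2093 at 12 h and 2429 at 18 h. Without the 9 embryos of unusual totals it was 966 at 12 h, 2587 at 18 h and 0 at 42 h, where embryo 58 alone was left out. A larger spread between embryos is argued against: the common coefficient of variation was 0.506 at 36 h, 0.505 at 18 h and 0.624 at 12 h. TMM scaling is argued against at 30 h by the 32 models and stays open at 42 h, as does a slowing of change in development, which was not tested separately.

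The difference between windows 4 and 5 may come in part from a difference between the number blocks. Models were called between parts of both windows and then measured in libraries not used for the call, over 20 random draws per selection. Called against window 4 embryos numbered 1 to 73, a choice that favours models that differ by block, they differed between the blocks within window 4 by a median log2 of 1.18 (middle 95% of draws 0.98 to 1.52) and changed from window 4 to 5 within embryos 74 to 123 by 0.10 (-0.03 to 0.28). Called against both blocks, which gave at least 10 models in 7 of 20 draws, these medians were 0.71 (0.25 to 1.29) and 0.56 (0.00057 to 1.07). Of the 333 models, 252 of the 282 testable within embryos 74 to 123 moved there in the same direction, with a median of 0.86 against 1.49 over both blocks, in libraries shared with the call, so the share that belongs to time stays open.

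Chance, in the sense of a random grouping of the embryos, could be excluded for most of the counts of changed models. This used other splits of the same embryos, 40 per comparison with the real split included. The real counts of 5381, 1303, 246 and 333 for the adjacent windows up to window 5 stood against highest other counts of 16, 12, 13 and 11. These splits ignored the number block and mixed the order of embryos in number and time. They cannot speak to differences between groups of embryos that lie close in number. Within embryos 1 to 73 the 204 models of window 4 against window 3 stood against a highest other of 7. Within embryos 74 to 123, however, 5 of 40 splits gave at least the 5 models of window 5 against window 4 (highest other 9), so chance was not excluded there. For window 6 against window 1 the real count of 6190 stood against 2, and for the matched pairs 255 against 14. Where chance was excluded, 1 split, the real one, gave as many. For window 6 against window 5 the real count was 0 and the highest other 5. All 40 splits reach a count of 0 by construction, so they say nothing about chance there.

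Principal component 2 (8.94% of the variance) was related to label time in early embryos and to the log2 gene to spike-in ratio in later ones. In windows 1 and 2 (n = 36) r against label time was -0.86 and rho -0.85 (permutation p = 1e-05 for each, the smallest it can give; adjusted p = 4e-05 and 3e-05 over 12 relations), and r was -0.87 without the 2 embryos farthest in time. Against the ratio r was -0.53 and rho -0.51 there (permutation p = 0.00016 and 0.0019, adjusted 0.00027 and 0.0028), and r was -0.59 without the 2 farthest. In windows 3 and 4 of embryos 1 to 73 (n = 36) r against the ratio was 0.80 and rho 0.82 (p = 1e-05 for each, adjusted 4e-05 and 3e-05), and r was 0.79 without the 2 farthest. With both adjusted for gene counts r was 0.77 and rho 0.71 (p = 1e-05 for each). In embryos 74 to 123 (n = 49) r was 0.58 and rho 0.61 (permutation p = 2e-05 and 1e-05, adjusted 6e-05 and 3e-05), and r was 0.54 without the 2 farthest. Against label time r was 0.18 (p = 0.30, adjusted 0.36) in windows 3 and 4 and 0.08 (permutation p = 0.57, adjusted 0.57) in embryos 74 to 123.

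Embryo 50, labelled -20 among neighbours in number of much later label times, was placed at 52 min by its nearest embryos. Embryo 27, labelled 1000 min, was placed at 268 min and had the lowest gene to spike-in ratio, 0.254, with 56536 gene counts.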
